A study of Homo sapiens with 4 samples.

How the data were processed

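RNA was measured in 4 libraries of sorted progenitors with an active PDX1 reporter, 1 library for each of 4 groups: before co-culture, and after co-culture with AKT-HUVEC, MPEC or BJ cells. Groups were taken from the co-culture label of each sample. Total RNA was extracted with a column kit, treated with DNase I and made into libraries by standard Illumina protocols, per the labels' protocols. Reads were aligned with TopHat2 2.0.0.7, and the build was hg19, per the submitters' processing notes. The deposited table gives FPKM per gene, meaning fragments scaled by transcript length and by the number of mapped fragments, in the column layout of a Cufflinks or Cuffdiff tracking table. The version of that software, its normalization between libraries and its handling of reads with several matches are not given in the sources used here. The authors' table also gives lower and upper confidence limits in FPKM for the AKT-HUVEC, MPEC and BJ libraries, at a level the sources used here do not state. A further 3 columns of values per sample have a name that matches no label, so they were not used, and the library before co-culture therefore has no limits here.

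The table had 23284 rows. Of these, 28 whose gene name had turned into a calendar date were left out, and 23256 genes were used. The values summed to 643502 before co-culture, 684593 for AKT-HUVEC, 672891 for MPEC and 670651 for BJ. The 1618 small RNA genes held 43.2%, 43.4%, 38.9% and 42.8% of these sums, and MIR4461 by itself held 29.1%, 31.1%, 24.0% and 31.2%. Such short genes take a large share of FPKM from few fragments. The depth was estimated from the steps between low values of 4928 single-transcript genes of at least 3000 bases, with lengths from GENCODE release 29. It came to 48.8, 49.5, 48.1 and 38.9 M fragments. Low values with BJ are therefore the least precise. An exact 0 in such a table can be a failed estimate, so a gene at 0 is only said to be listed at 0. Positions are those of the table in hg19, counted from 1, and a locus there can span overlapping genes.

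From the deposited FPKM values, log2((FPKM + 1) / (FPKM + 1)) was computed for 6 pairs of libraries. The pseudocount of 1 understates the ratio of low genes. Genes with at least 2 FPKM in the higher library were considered, and a ratio of at least 2-fold was called. With 1 library per group there is no p-value, and tests made for counts were not used. For 32 gene lists the median log2 ratio of members with at least 1 FPKM in some library was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and 31 lists had measured members. A median outside the central 95%, from the 2.5 to the 97.5 percentile, was said to stand apart. Small RNA genes were kept out of the random lists. Some lists share members, such as the neural list with both endocrine lists, so their medians are not independent. Genes higher or lower after all 3 co-cultures were compared with 200 simulations in which unchanged libraries shared the library before co-culture.

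The genes named were set by rule. PDX1 was given first. Among genes other than small RNA genes with at least 5 FPKM in the higher library, the rule took the 10 highest and 10 lowest after all 3 co-cultures, ranked by the smallest of the 3 ratios. It took also the 5 highest and 5 lowest of each co-culture against before, the 8 highest and 8 lowest of each against both others, and the 4 members of each list with the largest ratio in the comparison described. INS, GCG, SST, NEUROG3, NKX6-1, SOX9, PTF1A and MKI67 were always given. Some genes that the rule takes are not reported here. Genes named outside the rule are the 5 fibroblast genes under 1 FPKM, ELSPBP1, VIM, CNN1 and the members of the added lists, and all but the YAP targets were chosen after their values were seen.

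The groups, the lists, the rule for named genes and 8 alternatives were fixed before the data were examined. These were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 FPKM, scaling to 1 upper quartile, scaling by the median of ratios, scaling to a common sum as in TPM, and the same scaling without small RNA and mitochondrially encoded genes. Scaling as in TPM raises the values 1.46 to 1.55 times, and 2.43 to 2.73 times without small RNA genes, so the filter and the pseudocount weigh less and more list members pass the minimum of 1. Chosen after seeing the data were therefore the deposited values without small RNA genes, and these values at a common sum with their level and the list members kept. So were the use of the deposited limits, the shared genes without the MPEC library, and 4 further gene lists. Under the limits, a pair of co-cultures needed intervals that do not overlap, and a comparison with before needed the value before outside the co-culture interval. The value before, which has no limits here, was taken as exact. The calls were tested on simulated data for AKT-HUVEC against before with 23256 genes and noise of 0.36 SD on the log2 scale. Of 50 genes changed 1.5-fold, 2 were recovered. At 3-fold 43 of 50 were recovered, and at 6-fold and 12-fold all 50. Of 23056 unchanged genes 27 were called, and 11 of 200 random lists stood apart. The 23056 include genes under the filter of 2 FPKM, which cannot be called. The simulated noise was the same at every level of expression. The ratios of this pair had an SD of 0.78 over considered genes, real changes included. The 27 therefore do not tell how many of the real calls are noise. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.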

Results

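The study measured RNA from sorted pancreatic progenitors carrying a green fluorescent reporter of PDX1, a transcription factor of the early pancreas. The progenitors were made from HUES8, an established human embryonic stem cell line. The series held 4 RNA-seq libraries with 1 library per group. They were progenitors before co-culture and progenitors sorted after co-culture with AKT-HUVEC, MPEC or BJ cells. HUVEC are endothelial cells of the human umbilical vein and BJ is a human foreskin fibroblast line. The labels do not spell out MPEC and it is left unexpanded here. Values were FPKM, and the estimated depth was 48.8 M fragments before co-culture, 49.5 M for AKT-HUVEC, 48.1 M for MPEC and 38.9 M for BJ. There were no replicates in any group, so no difference below has a replicate check, and each ratio compares 2 libraries rather than 2 conditions. No group held progenitors cultured further without a partner. A difference from before can therefore not be told apart from an effect of time or conditions in culture. A gene is called higher or lower when its ratio on the FPKM + 1 scale reached 2-fold and its value was at least 2 FPKM in the higher library. A list of genes is said to stand apart when its median log2 ratio lay outside the central 95% of 10000 random lists matched on expression. The members of a list tend to move together, which the random lists do not, so this describes these libraries only.

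The reporter's own gene was present in every library, which the sort for that reporter selects for. PDX1, at chromosome 13, 28494168 to 28500451 in hg19, had 42.2 FPKM before co-culture, 36.4 with AKT-HUVEC, 75.6 with MPEC and 28.8 with BJ, all within 2-fold of the value before. With MPEC it was past 2-fold higher than with AKT-HUVEC and than with BJ. SOX9, a progenitor and duct factor, had 31.5, 37.3, 59.2 and 39.3 FPKM in the same order. NKX6-1, a factor of later progenitors and beta cells, was low throughout, at 0.15, 0.31, 1.31 and 0.054 FPKM. PTF1A, a factor of acinar and early progenitor cells, had 0.10 FPKM before co-culture and 0.017 with MPEC, and it was listed at 0 in the other 2 libraries. Of 28 measured pancreatic progenitor transcription factors, 2 were higher with MPEC, and 0 were past 2-fold with AKT-HUVEC or BJ. The list's median log2 ratio against before was -0.15 with AKT-HUVEC, 0.31 with MPEC and -0.26 with BJ, each outside the random range. With MPEC it lay inside that range with a pseudocount of 5, at 0.23, or a filter of 5 FPKM, at 0.30. ONECUT2 of that list had 5.38 FPKM before co-culture and 45.6 with MPEC.

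**Figure D1:**
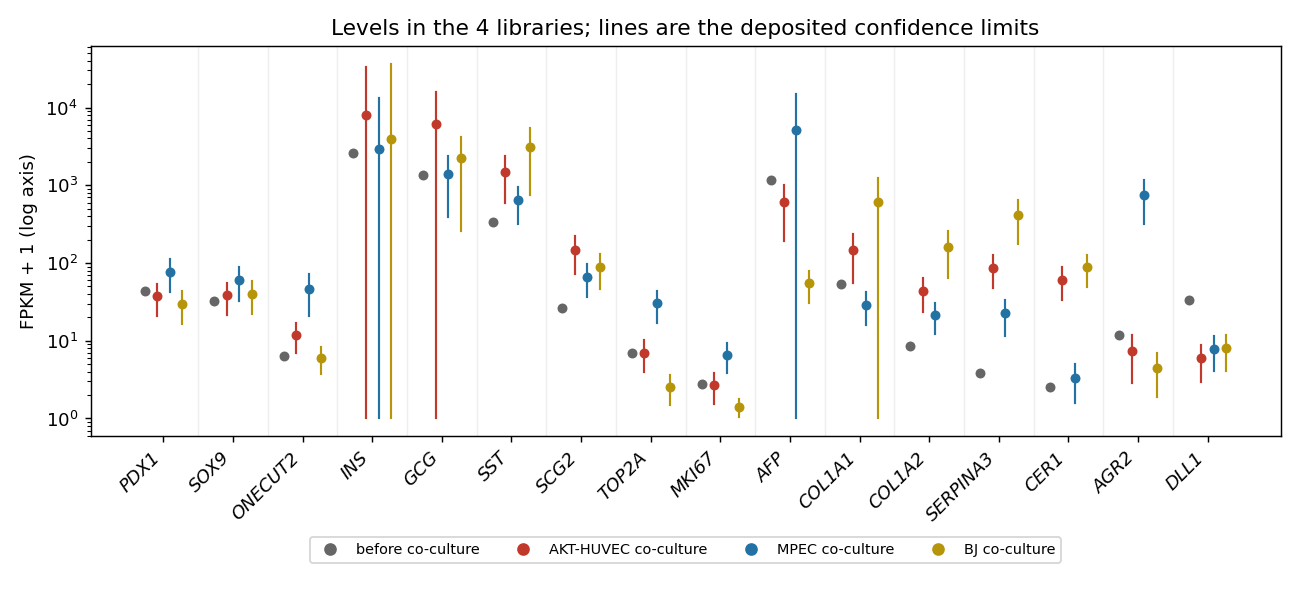
FPKM plus 1 on a log axis for 16 named genes in the 4 libraries, with points for single libraries and lines for the deposited confidence limits, which are not used for the library before co-culture. AGR2 stood at 738 FPKM with MPEC and at 10.7 before, while INS had limits reaching down to 0 in all 3 co-culture libraries.

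The first question was how progenitors differed after co-culture with AKT-HUVEC cells from those before. Genes for pancreatic hormones and their secretory granules were higher: 16 of 33 measured members were called higher and 0 lower. The list's median log2 ratio was 0.99 against a random range of -0.08 to 0.20. GCG, which encodes glucagon, had 1347 FPKM before and 6221 after. SST, for somatostatin, had 332 and 1481 FPKM, PPY, for pancreatic polypeptide, 1.89 and 27.8, and the granule gene SCG2 25.3 and 146. INS, for insulin, had 2633 FPKM before and 8076 after, but its deposited limits of 0 to 33303 enclosed the value before. The limits of GCG, 0 to 15764, did so too. INS overlaps INS-IGF2 in the table, which had at most 0.051% of the INS value in any library. Transcription factors of endocrine progenitors lay inside the random range, with a median of 0.09, 2 of 23 called higher and 0 lower. IRX1 had 3.94 FPKM before and 12.2 after, IRX2 7.64 and 16.2, and NEUROG3, the factor that starts the endocrine programme, 1.98 and 0.30.

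Genes of cholesterol and fatty acid synthesis were lower with AKT-HUVEC, with 10 of 28 called lower, 0 higher and a median of -0.80. HMGCS1, of the sterol pathway, had 111 FPKM before and 45.3 after, and SQLE had 65.6 and 26.2. Replication-dependent histone genes, a list fixed as a sign of RNA quality and tail selection, stood apart in all 3 comparisons with before, at 0.62 with AKT-HUVEC, -0.52 with MPEC and 0.80 with BJ. With AKT-HUVEC 4 of 12 were called higher. HIST1H2AC among them had 8.42 FPKM before and 36.7 after. Interferon response genes had a median of 0.56 with 3 of 27 higher, among them OAS1 at 0.30 and 4.02 FPKM. Smaller medians also stood apart. They were 0.37 for cell cycle inhibitors and p53 targets, 0.36 for the unfolded protein and integrated stress response, 0.28 for epithelial adhesion genes and 0.22 for extracellular matrix genes. On the lower side they were -0.39 for immediate early genes, -0.32 for Wnt targets, -0.20 for hypoxia and glycolysis, -0.16 for intestinal and gastric genes, -0.15 for liver genes and -0.09 for cell cycle genes. With a filter of 5 FPKM the intestinal list was at 0.010, and the Wnt list, at -0.16, lay inside the random range. The intestinal list did so under median of ratios scaling, at -0.18, and without small RNA genes at the deposited level, at -0.21. The matrix list did so with no filter, at 0.19, and without small RNA genes on the TPM scale, at 0.12. The genes with the largest ratios were RPL21, CER1, SERPINA3, LEFTY2 and CA4 on the higher side. CER1, an inhibitor of Nodal and BMP ligands, had 1.57 and 60.3 FPKM, LEFTY2, a Nodal inhibitor, 0.85 and 24.96, and CA4, a carbonic anhydrase, 1.98 and 30.3. On the lower side were MMP1, a collagenase, at 199 and 19.3 FPKM, CLCA1 at 7.64 and 0.19, and TF, for transferrin, at 57.9 and 8.52. H3F3A and SNAR-G2 were listed at 0 after co-culture. In all, 574 genes were higher and 293 lower of 12950 considered. Asking also that the value before lie outside the deposited limits left 318 higher and 241 lower, and a pseudocount of 5 left 257 higher and 186 lower. Small RNA genes were among those called, and leaving them out of the deposited values left 455 higher and 160 lower.

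With MPEC, genes of cell division were higher than before. Of 48 measured cell cycle genes 27 were called higher and 0 lower, and the median log2 ratio was 1.04 against a random range of -0.03 to 0.26. TOP2A, a DNA topoisomerase of dividing cells, at chromosome 17, 38544773 to 38574202, had 5.96 FPKM before and 29.3 after. RRM2, for making deoxynucleotides, had 8.31 and 30.1 FPKM, and MKI67, a marker of cycling cells, 1.75 and 5.63. Transcription factors of endocrine progenitors were lower, with 10 of 23 called lower, 0 higher and a median of -0.76. NKX2-2 had 28.6 FPKM before and 3.48 after, INSM1 50.3 and 7.12, and NEUROD1 32.3 and 7.49. Hormone and granule genes went both ways, with 3 higher and 4 lower of 33, a median of -0.16 that stood apart and a mean of 0.01 of the other sign. Replication-dependent histone genes, the sign of RNA quality and tail selection, had a median of -0.52 in this library, with 0 of 12 higher and 2 lower.

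Further lists stood apart in the MPEC library. On the higher side, interferon response genes had a median of 0.64 with 12 of 27 called higher, FGF and EGF targets 0.51 with 9 of 25, duct genes 0.51 with 5 of 22, and epithelial adhesion genes 0.49 with 8 of 26. Ribosomal protein genes had a median of 0.49 with 2 of 73 called higher. The median of pluripotency genes was 0.46 with 3 of 15 higher and 1 lower. It was 0.06 with no filter and 0.06 on the TPM scale, inside the random range in both, and -0.02 on the TPM scale without small RNA genes. More members are counted in these settings, and for the same 15 members at the deposited level without small RNA genes it was 0.34. CFTR, a chloride channel of duct cells, had 1.65 FPKM before and 8.41 after. On the lower side, genes of epithelial to mesenchymal transition had a median of -0.68 with 7 of 20 called lower, and TGFB2 among them had 37.8 and 4.12 FPKM. Endothelial markers had a median of -0.58, neural genes -0.57, immediate early genes -0.52, acinar genes -0.28, extracellular matrix genes -0.27, cholesterol synthesis genes -0.20, hypoxia and glycolysis genes -0.19 and TGF-beta and BMP targets -0.12. The endothelial median was 0.0033 with a filter of 5 FPKM, and the acinar list lay inside the random range with a pseudocount of 5, at -0.09, or no filter, at -0.06. Among TGF-beta and BMP targets the members parted. ID2 and ID3, targets of BMP signals, had 68.3 and 126 FPKM before and 574 and 485 after, while CTGF and CYR61 had 293 and 270.2 before and 61.6 and 57.6 after. AGR2, a protein disulfide isomerase of secretory epithelia, had 10.7 FPKM before and 738 after, TDO2, which breaks down tryptophan, 1.14 and 132, S100P 1.38 and 91.8, and CALB1, a calcium-binding protein, 4.08 and 151. Among lower genes, TIMP3, an inhibitor of metalloproteinases, had 87.4 and 2.39 FPKM, ACTA1 32.7 and 0.32, and ACTC1 39.2 and 1.04. In all, 917 genes were higher and 506 lower of 13000 considered. The deposited limits left 568 higher and 449 lower, a pseudocount of 5 left 424 and 259, and leaving out small RNA genes left 787 and 370. With the rest on the TPM scale there were 800 higher and 858 lower, or 48.3% higher of those called against 64.4%, and with the common sum at the deposited level 579 and 499, or 53.7%.

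With BJ cells, interferon response and inflammatory genes were higher than before. Of 27 measured interferon response genes 19 were called higher and 0 lower, with a median log2 ratio of 1.36 against a random range of -0.17 to 0.24. IFI6 had 8.36 FPKM before and 123 after, and BST2 had 0.53 and 12.5. Inflammatory and NF-kB genes had a median of 1.19 with 14 of 22 higher. The chemokine CCL2 had 7.11 and 88.4 FPKM, and the adhesion molecule ICAM1 4.18 and 45.1. Fibroblast and mesenchyme markers were also higher, with 13 of 27 called higher, 0 lower and a median of 1.01. COL1A1, a chain of type I collagen at chromosome 17, 48261457 to 48279000, had 52.4 FPKM before and 599.6 after, and COL1A2 had 7.58 and 159. The listed markers left unmeasured, DCN, DPT, PRRX1, TBX15 and TWIST2, were by that definition under 1 FPKM in every library. Before and with BJ, PRRX1 had 0.020 and 0.45 FPKM, DCN 0.13 and 0.79, TBX15 0.54 and 0.39 and TWIST2 0.059 and 0.074. DPT was listed at 0 in both. Cell cycle genes were lower, with 31 of 48 called lower, 0 higher and a median of -1.11. UBE2C had 17.3 and 3.79 FPKM, FOXM1 11.6 and 2.33, and MKI67 1.75 and 0.40. Liver genes were lower too, with 12 of 22 called lower, 1 higher and a median of -1.22. AFP, for alpha-fetoprotein, had 1162 FPKM before and 53.6 after, and ALB, for albumin, 22.2 and 1.22.

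Other lists stood apart in the BJ library. Hormone and granule genes had a median of 0.58 with 7 of 33 called higher and 2 lower. SST had 332 and 3112 FPKM, SNAP25, of vesicle fusion, 9.20 and 35.1, and IAPP, for islet amyloid polypeptide, 9.08 and 1.70. Replication-dependent histone genes, the sign of RNA quality and tail selection, had a median of 0.80, genes of epithelial to mesenchymal transition 0.71, neural genes 0.63, cell cycle inhibitors and p53 targets 0.45, extracellular matrix genes 0.43, the unfolded protein and integrated stress response 0.42, immediate early genes 0.39, epithelial adhesion genes 0.36 and duct genes 0.31. On the lower side, cholesterol synthesis genes had a median of -0.60, intestinal and gastric genes -0.59, pluripotency genes -0.36, ribosomal protein genes -0.25 and genes of definitive endoderm -0.24. The means of the pluripotency and definitive endoderm lists, 0.08 and 0.05, had the other sign. With a filter of 5 FPKM the intestinal list, at -0.16, the duct list, at 0.29, and the definitive endoderm list, at -0.12, lay inside the random range. The definitive endoderm list did so too with a pseudocount of 0.1, at -0.25, and under median of ratios scaling, at -0.27. CDKN2B, a cell cycle inhibitor, had 24.2 FPKM before and 129 after, and the keratin KRT7 9.53 and 95.7. By size alone, SERPINA3, an acute phase protease inhibitor at chromosome 14, 95078714 to 95090390, had 2.90 FPKM before and 412 after, and PTHLH, for a parathyroid hormone related protein, 2.87 and 91.1. MMP1 had 199 and 5.34 FPKM, and ANXA13 31.7 and 0.85. VTRNA1-3 was listed at 0 with BJ. In all, 820 genes were higher and 594 lower of 12990 considered. The deposited limits left 560 higher and 527 lower, and a pseudocount of 5 left 440 and 299.

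**Figure D2:**
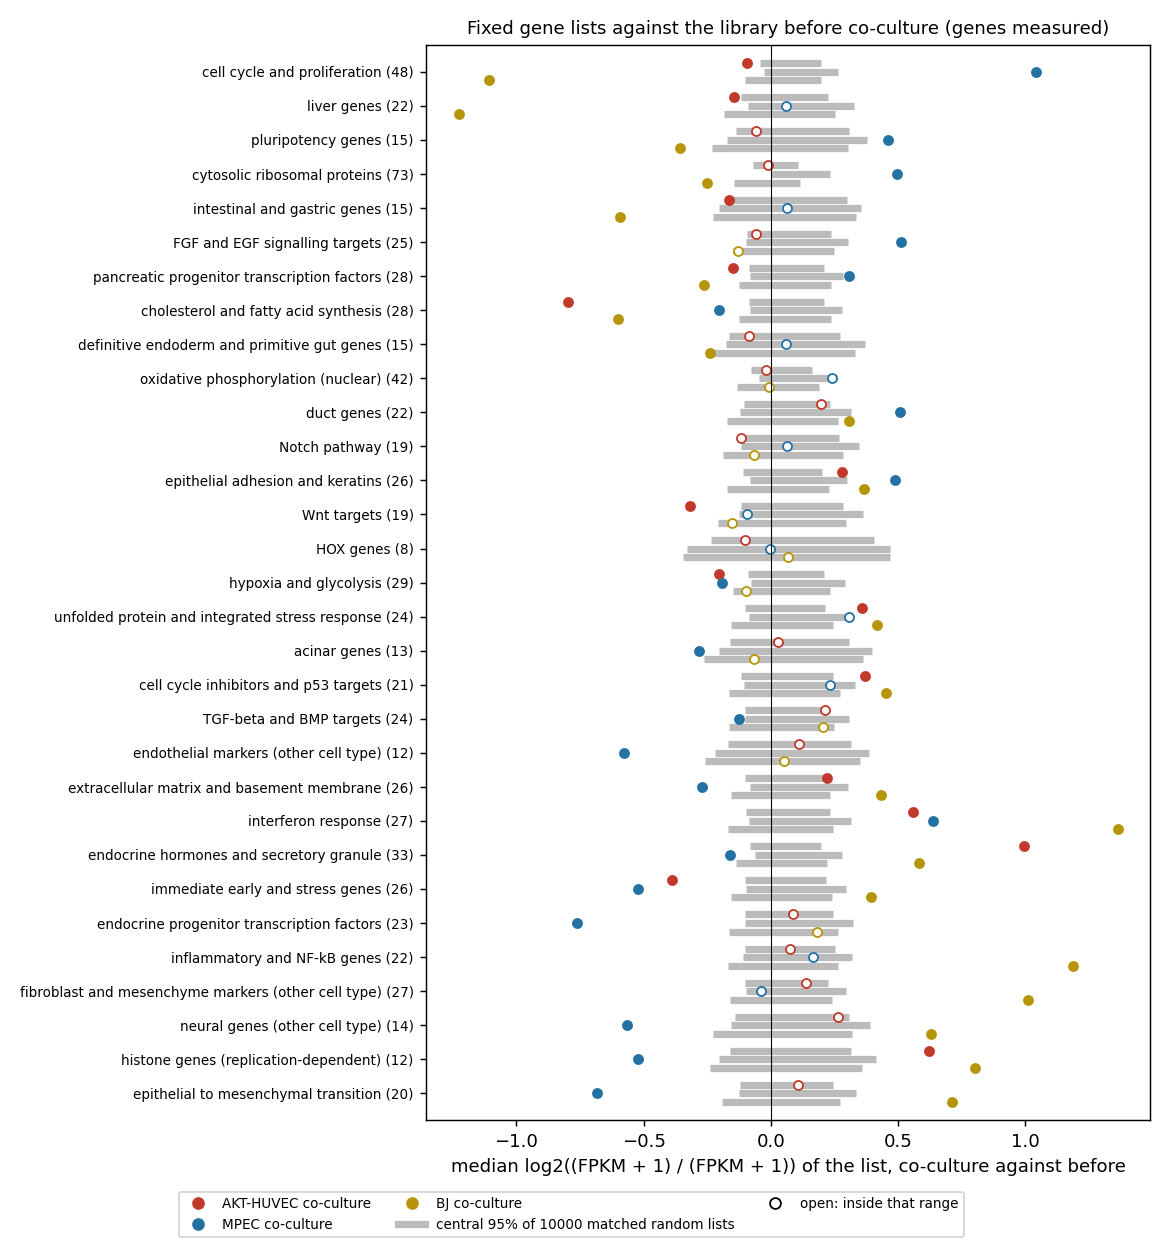
Median log2 ratio against the library before co-culture for 31 gene lists, with the number of genes measured in brackets, 1 point per co-culture and grey bars for the central 95% of 10000 matched random lists. Cell cycle genes lay at 1.04 with MPEC and -1.11 with BJ, and interferon response genes lay above the bars in all 3.

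The remaining lists lay inside the random range in the comparisons with before. HOX genes had medians of -0.10 with AKT-HUVEC, -0.00 with MPEC and 0.07 with BJ, and the Notch pathway -0.12, 0.06 and -0.06. Nuclear genes of oxidative phosphorylation had -0.02, 0.24 and -0.01, with 0 of 42 past 2-fold in each. Inside the range were also acinar genes with AKT-HUVEC and BJ at 0.03 and -0.07, FGF and EGF targets at -0.06 and -0.13, and TGF-beta and BMP targets at 0.21 and 0.20. Definitive endoderm genes had -0.09 with AKT-HUVEC and 0.06 with MPEC. Wnt targets had -0.09 with MPEC and -0.15 with BJ, and inflammatory genes 0.08 with AKT-HUVEC and 0.17 with MPEC. Fibroblast markers had 0.14 and -0.04, endothelial markers 0.11 with AKT-HUVEC and 0.05 with BJ, and neural genes 0.26 with AKT-HUVEC. Endocrine progenitor factors had 0.18 with BJ, ribosomal protein genes -0.01, pluripotency genes -0.06 and duct genes 0.20 with AKT-HUVEC. With MPEC, liver genes had 0.06, intestinal and gastric genes 0.07, cell cycle inhibitors and p53 targets 0.23 and the unfolded protein response 0.31. Mean and median differed in sign for the acinar list with AKT-HUVEC and BJ, for the Wnt list with BJ, and for the definitive endoderm list with AKT-HUVEC and MPEC. They also differed for the endothelial, pluripotency, ribosomal and oxidative phosphorylation lists with AKT-HUVEC, and for the Notch, HOX, p53 and intestinal lists with MPEC. Of 38 endothelial markers 12 reached 1 FPKM in any library. The 13 mitochondrially encoded genes were not analysed here.

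Several of these remaining lists stood apart under other settings. With AKT-HUVEC and a filter of 5 FPKM, FGF and EGF targets were at -0.40, inflammatory genes at 0.31 and neural genes at 0.42. The Notch pathway, whose median lay at the edge of its range, stood apart in 4 of 8 settings, at -0.21 to -0.10, and without small RNA genes at the deposited level, at -0.20. Fibroblast markers did so in 3, at 0.20 to 0.35, duct genes in 2, at 0.20 and 0.32, TGF-beta and BMP targets with a pseudocount of 5, at 0.16, and pluripotency genes with no filter, at -0.11. With MPEC, the unfolded protein response stood apart in 4 of 8 settings, at 0.14 to 0.31, Wnt targets on the TPM scale without small RNA genes, at -0.31, and fibroblast markers with a pseudocount of 0.1, at -0.31. Liver genes with MPEC turned to -0.19 with a filter of 5 FPKM. With BJ, that filter turned Wnt targets to 0.51 and acinar genes to 1.30, a pseudocount of 0.1 put FGF and EGF targets at -0.17, and a pseudocount of 5 put TGF-beta and BMP targets at 0.19, all outside the range. The endothelial list with BJ stood apart on the lower side with no filter, at -0.09, and without small RNA genes on the TPM scale, at -0.44, but it was -0.0033 for the same 12 members at the deposited level.

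The next question was which genes differed from before in the same direction in all 3 co-cultures. LEFTY1, a Nodal inhibitor, had 1.93 FPKM before and 20.8 with AKT-HUVEC, 18.4 with MPEC and 17.4 with BJ. SERPINA5, a protease inhibitor, had 9.30 before and 83.6, 61.0 and 133, SERPINA3 2.90 and 86.0, 21.7 and 412, LGALS3BP 14.9 and 78.2, 76.1 and 128, and the integrin ITGB6 8.58 and 36.5, 50.1 and 60.03. The long noncoding RNA UCA1 had 1.11 before and 14.5, 53.7 and 10.6, TTYH1 0.84 and 9.98, 20.3 and 11.4, GC, for vitamin D binding protein, 0.70 and 11.9, 5.87 and 5.15, and GGT1 2.10 and 9.50, 18.1 and 10.7. RPL21, a ribosomal protein with many pseudogenes, had 0.0099 FPKM before and 49.4, 94.9 and 25.3, with limits down to 0 in all 3, and is uncertain. Lower in all 3, the Notch ligand DLL1 had 32.3 FPKM before and 4.97, 6.73 and 6.98, and MLN, for the gut hormone motilin, 19.1 and 2.63, 1.97 and 2.09. The muscle actins ACTC1 and ACTG2 had 39.2 and 14.7 before, 7.01 and 1.71 with AKT-HUVEC, 1.04 and 0.98 with MPEC, and 5.54 and 2.49 with BJ. CLCA1 had 7.64 before and 0.19, 0.15 and 0.075, and ACTA1 32.7 and 7.85, 0.32 and 5.43. The pepsinogen genes PGA3, PGA4 and PGA5 had 45.3, 54.4 and 71.9 before and at most 11.9, 14.6 and 19.6 after, and these near-identical copies cannot be told apart with confidence. SNAR-G2 was listed at 0 in all 3. In all, 129 genes were higher and 91 lower after all 3. With no progenitors cultured without a partner, genes shared by all 3 cannot be told apart from an effect of time in culture. These ratios share 1 library before co-culture. Simulated unchanged libraries, given the spread among the 3 co-cultures, which includes differences between partners, shared a mean of 243 higher genes with a range of 199 to 278, and a mean of 311 lower genes with a range of 260 to 360. Independent lists of these sizes would share 2.77 and 0.56 genes. The simulated 311 exceeds the 293 genes called lower with AKT-HUVEC in all, so the spread used is too wide for unchanged libraries, and these values do not show whether the observed sharing exceeds chance. Part of any excess over independent lists may come from the shared library. The deposited limits left 65 genes higher, a pseudocount of 5 left 52 and 59, leaving out small RNA genes left 102 and 39, and without the MPEC library 339 were higher and 173 lower.

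**Figure D3:**
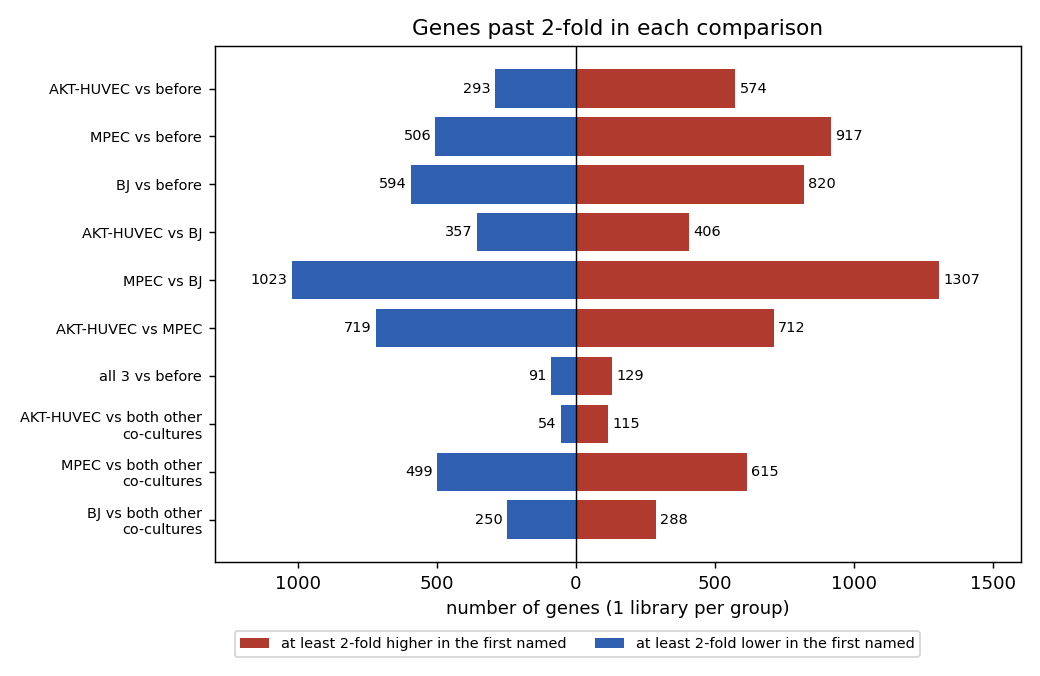
Number of genes at least 2-fold higher to the right and lower to the left in the first named library of each comparison, with 1 library per group. The MPEC and BJ libraries differed by 1307 and 1023 genes, and the AKT-HUVEC and BJ libraries by 406 and 357.

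The co-cultures were then compared with each other. The MPEC and BJ libraries differed most in number, with 1307 genes higher in MPEC and 1023 lower of 13263 considered. Without small RNA genes on the TPM scale there were 1296 higher and 1477 lower, or 46.7% higher of those called against 56.1%, and at the deposited level 983 and 1017, or 49.2%. Of 48 cell cycle genes 43 were higher in MPEC and 0 lower, with a median of 2.03, and BIRC5 had 25.6 FPKM in MPEC and 2.37 in BJ. Liver genes had a median of 1.27 with 15 of 22 higher, intestinal and gastric genes 0.99 with 6 of 15 higher and 5 lower, ribosomal protein genes 0.76, pancreatic progenitor factors 0.57, pluripotency genes 0.52 and FGF and EGF targets 0.49. Lower in MPEC than in BJ were genes of epithelial to mesenchymal transition at -1.80, fibroblast markers at -1.69, histone genes at -1.502, neural genes at -1.48, endocrine progenitor factors at -1.21 with 14 of 23 called lower, inflammatory genes at -1.17, TGF-beta and BMP targets at -0.89, hormone and granule genes at -0.76, interferon response genes at -0.76, immediate early genes at -0.58 and extracellular matrix genes at -0.23. Histone genes were the list fixed as a sign of RNA quality and tail selection. The snail family factor SNAI2 had 0.20 FPKM in MPEC and 13.5 in BJ. The mean of the Wnt list, -0.38, and its median, 0.11, which lay inside the random range, differed in sign. With a filter of 5 FPKM the Wnt list turned to -1.19, standing apart, and the intestinal list to -0.44, and the acinar list, at -0.15 and inside the range, went to -2.90. The acinar list stood apart also with a pseudocount of 0.1, at -1.09, and on the TPM scale, at -0.41, the endothelial list with a pseudocount of 0.1, at -0.55 against -0.34, and oxidative phosphorylation genes with no filter, at 0.23. Pluripotency genes lay inside the range with no filter, at 0.07, and with a filter of 5 FPKM, at 0.52. A pseudocount of 5 left 662 genes higher and 540 lower, and intervals that do not overlap left 459 and 427.

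Between AKT-HUVEC and BJ, 406 genes were higher and 357 lower in AKT-HUVEC of 12975 considered. Cell cycle genes had a median of 0.93 with 17 of 48 higher, liver genes 0.68 with 9 of 22 and hormone and granule genes 0.35 with 7 of 33. Fibroblast markers had -1.02 with 14 of 27 lower, inflammatory genes -0.99, genes of epithelial to mesenchymal transition -0.95 and interferon response genes -0.74. Other lists lower in AKT-HUVEC were immediate early genes at -0.50, neural genes at -0.34, FGF and EGF targets at -0.30, TGF-beta and BMP targets at -0.26, cholesterol synthesis genes at -0.26, cell cycle inhibitors and p53 targets at -0.20, the Notch pathway at -0.18, histone genes at -0.18, Wnt targets at -0.13 and extracellular matrix genes at -0.12. Ribosomal protein genes, at 0.23, and pancreatic progenitor factors, at 0.11, were higher. Mean and median differed in sign for the acinar, definitive endoderm, endothelial and endocrine progenitor lists, which lay inside the random range. With a filter of 5 FPKM the acinar list turned from 0.09 to -1.04, standing apart. Inside the range, but apart in some settings, were intestinal genes in 5 of 8, at 0.18 to 0.39, pluripotency genes in 4, at 0.14 to 0.27, and without small RNA genes at the deposited level, at 0.21, endothelial markers in 2, at 0.05 and 0.21, and HOX genes with a pseudocount of 0.1, at -0.39. Apart, but not in all settings, were histone genes, inside the range in 3 at -0.21 to -0.10 and at 0.0092 with no filter, pancreatic progenitor factors, inside it in 2 at 0.07 and 0.08, and Wnt targets, inside it with a pseudocount of 5 at -0.06. A pseudocount of 5 left 214 and 211 genes, leaving out small RNA genes 253 and 236, and intervals that do not overlap left 66 and 70.

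Between AKT-HUVEC and MPEC, 712 genes were higher and 719 lower in AKT-HUVEC of 13167 considered. Endocrine progenitor factors had a median of 1.35 with 14 of 23 higher in AKT-HUVEC and 1 lower, and hormone and granule genes 1.31 with 22 of 33 higher and 0 lower. ISL1, a factor of endocrine cells, had 63.0 FPKM in AKT-HUVEC and 17.2 in MPEC, NEUROD1 32.6 and 7.49, and CHGB 36.4 and 9.88. Histone genes, the sign of RNA quality and tail selection, had a median of 1.04 with 6 of 12 higher and 0 lower. Markers of other cell types stood apart on the same side, neural genes at 0.72, fibroblast markers at 0.42 and endothelial markers at 0.35. The neural list shares members with both endocrine lists, and the endothelial list with the pancreatic progenitor list, so these medians are not independent of them. So did acinar genes at 0.63, TGF-beta and BMP targets at 0.60, genes of epithelial to mesenchymal transition at 0.58, extracellular matrix genes at 0.37, Wnt targets at 0.27, the unfolded protein response at 0.16 and cell cycle inhibitors and p53 targets at 0.15. Cell cycle genes had -1.14 with 32 of 48 lower, liver genes -0.70, FGF and EGF targets -0.64, cholesterol synthesis genes -0.54, ribosomal protein genes -0.52, pancreatic progenitor factors -0.44, the Notch pathway -0.38, interferon response genes -0.28 and oxidative phosphorylation genes -0.20. Mean and median differed in sign for the hypoxia and inflammatory lists. Lists that lay inside the random range in some settings were endothelial markers in 3, at 0.21 to 0.37, interferon response genes in 2, at -0.28 and -0.15, p53 targets in 2, both at 0.13, acinar genes with no filter, at 0.04, and Wnt targets and oxidative phosphorylation genes with a pseudocount of 5, at 0.11 and -0.18. Inside the range, but apart in some settings, were duct genes in 3, at -0.26 to -0.17, immediate early genes in 2, at 0.14 and 0.15, and inflammatory genes in 2, at 0.18 and 0.21. The intestinal list turned from -0.15 to 0.43, standing apart, with a filter of 5 FPKM. A pseudocount of 5 left 367 and 365 genes, and intervals that do not overlap left 212 and 169. Without small RNA genes on the TPM scale there were 1021 higher and 674 lower, or 60.2% higher of those called against 49.8%, and at the deposited level 641 and 488, or 56.8%.

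Each co-culture library was last set against both others. With MPEC, 615 genes were higher and 499 lower than in both, and without small RNA genes on the TPM scale there were 608 and 794. AGR2, TDO2, MMP1, CALB1, IL33, MMP10, S100P and FABP1 led the higher side. MMP1 had 1144 FPKM with MPEC, 19.3 with AKT-HUVEC and 5.34 with BJ, IL33, a cytokine of epithelia, 35.3, 0.27 and 0.18, MMP10 165, 4.93 and 4.72, and FABP1, a fatty acid carrier, 113, 3.22 and 1.002. CER1, PTHLH, CDKN2B, EDN1, PRSS2, TIMP3, NPFFR2 and FAM65B led the lower side. CDKN2B had 5.40 FPKM with MPEC, 77.4 with AKT-HUVEC and 129 with BJ, and EDN1, for endothelin, 3.52, 43.4 and 52.6. With BJ, 288 genes were higher and 250 lower than in both others. The trypsinogen genes PRSS1, PRSS2, PRSS3 and TRY6 had 1591, 1016, 140.3 and 562 FPKM with BJ and 121, 69.1, 11.4 and 41.2 with AKT-HUVEC. Near-identical copies make the single values uncertain. COL6A3, a collagen chain, had 8.31 FPKM with BJ and at most 0.28 with the others, LGALS1 50.9 and at most 6.50, the metallothionein MT1G 30.5 and at most 4.17, and the noncoding RNA MIAT 24.0 and at most 3.19. CA4, LCN15, AFP, CKB and GSTA2 were lower with BJ, CKB with 109.9 FPKM against 935 and 2261, and VTRNA1-1 and VTRNA1-3 were listed at 0. With AKT-HUVEC, 115 genes were higher and 54 lower than in both others. FLT1, a receptor of VEGF, had 47.7 FPKM against 10.9 with MPEC and 15.001 with BJ, FFAR1, a fatty acid receptor of islets, 16.3 against 4.90 and 3.62, GCG 6221 against 1396 and 2221, and SYBU 6.39 against 0.46 and 1.37. Among genes lower than in both, AREG had 8.83 FPKM against 30.5 and 23.0, FOS 27.7 against 62.9 and 86.3, IGFBP3 58.2 against 120.3 and 122, IGFBP4 5.93 against 13.1 and 24.4, SCD 40.5 against 108 and 81.3, SNCAIP 2.11 against 6.30 and 6.11, and BST2 3.03 against 6.93 and 12.5. H3F3A, which has near-identical copies, was listed at 0. Leaving small RNA genes out of the deposited values left 31 and 9 genes for AKT-HUVEC, and with the rest on the TPM scale there were 58 and 17. Intervals that do not overlap left 5 higher and 0 lower for AKT-HUVEC, 154 and 161 for MPEC, and 60 and 46 for BJ. The 5 were ELSPBP1, KCNJ8 at 40.6 FPKM against 14.4 and 8.93, LOC100506013 at 37.2 against 8.31 and 4.24, SLC22A3 and TYRP1, of which ELSPBP1 was named after its values were seen. A gene higher than in both others need not be higher than before. Before and with AKT-HUVEC, ELSPBP1 had 1.16 and 2.11 FPKM, KCNJ8 24.9 and 40.6, LOC100506013 8.88 and 37.2, SLC22A3 17.3 and 10.02, and TYRP1 1.52 and 6.48. Of these, LOC100506013 and TYRP1 were past 2-fold against before. FLT1 was not called higher than before either.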

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

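The tests on carried-over cells and on the share of endocrine cells were chosen only after the results they bear on were seen, and those on scaling and on the hormone genes before. Lists are given here because their medians against the library before co-culture stood apart in opposite directions in different co-cultures. With 1 library per group these differences were not tested.

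Cell cycle genes had a median log2 ratio of -0.0943 with AKT-HUVEC, 1.0422 with MPEC and -1.1086 with BJ. Under the 4 other scalings the median stayed between 0.92 and 1.02 with MPEC and between -1.42 and -1.14 with BJ, so that its smallest size was 0.9204. These scalings differ too little between libraries to bring such medians near 0, so the outcome was fixed in advance. It shows only that none of these 4 accounts for the medians. Dilution by carried-over BJ cells would lower epithelial genes as much, but their median with BJ was 0.3649 and their lower quartile -0.03. Carried-over MPEC cells cannot be told apart from a change in the progenitors, since the labels give neither the type nor the organism of MPEC. Endothelial markers, should MPEC be endothelial, had a median of -0.5779 with an upper quartile of 0.01, and a median of 0.0033 with a filter of 5 FPKM. A response of the progenitors to each partner and a different mix of sorted cells stay open and untested. So does a difference in RNA quality or tail selection. The histone list fixed as its sign stood apart the other way, at -0.52 with MPEC and 0.80 with BJ.

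Hormone and granule genes had medians of 0.9948 with AKT-HUVEC, -0.1624 with MPEC and 0.5807 with BJ. For AKT-HUVEC the lowest median over the 4 other scalings was 0.9057, and without 6 hormone genes it was 0.774 over 27 members. The higher median thus does not rest on these 6 genes alone or on the choice among these scalings. The scalings differ too little between libraries to bring it near 0. A median counts each gene once, whatever its abundance, so it is a weak test for a few abundant genes. A larger share of endocrine cells by itself might raise endocrine transcription factors about as much. Their upper quartile was 0.5126 and their median 0.09. That list mixes factors that were lower, such as NEUROG3, with ones that were higher, such as IRX1 and IRX2. Its members need not all follow the number of hormone cells, so it cannot decide this. A larger share of endocrine cells, a change within them, or a shift towards some of them only may account for the higher granule genes and stays open. The deposited limits of INS and GCG still enclosed the values before co-culture.

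Genes of epithelial to mesenchymal transition had medians of -0.6832 with MPEC and 0.71 with BJ, and the fibroblast list had 1.01 with BJ. Under other settings that list also stood apart with AKT-HUVEC, at 0.20 to 0.35 in 3 of 8, and with MPEC, at -0.31 in 1. The lowest fibroblast median with BJ over the 4 other scalings was 0.9503. Here too the scalings differ too little to bring it near 0, so this shows only that none of the 4 accounts for it. Both carried-over BJ cells, which the sort for the PDX1 reporter would remove, and collagen made by the sorted cells stay open, since no library of BJ cells by itself was analysed here to give the level of each gene in them. With BJ, COL1A1 had 599.6 FPKM and LGALS1 50.9, while the fibroblast genes DCN, PRRX1, TBX15 and TWIST2 had 0.79, 0.45, 0.39 and 0.074 and DPT was listed at 0. These low genes are the list members under 1 FPKM in every library, so their low level is by selection and does not decide between the 2. COL1A1 also had 147 FPKM with AKT-HUVEC, where no fibroblast partner is named, and VIM had 1086 FPKM before and 857 with BJ.

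Ribosomal protein genes had medians of 0.4945 with MPEC and -0.2496 with BJ. Extracellular matrix genes had 0.2205 with AKT-HUVEC, -0.2724 with MPEC and 0.4332 with BJ. Replication-dependent histone genes had 0.6225, -0.5213 and 0.8036 in that order, and immediate early genes -0.3877, -0.5221 and 0.3925. Pancreatic progenitor factors had -0.1475, 0.3075 and -0.2621. Neural genes had -0.5657 with MPEC and 0.6305 with BJ, and pluripotency genes 0.4588 and -0.357. Of these, extracellular matrix genes with AKT-HUVEC, and pancreatic progenitor factors and pluripotency genes with MPEC, did not stand apart in every setting. Among single genes, 38 were past 2-fold in opposite directions against before with AKT-HUVEC and MPEC, 23 with AKT-HUVEC and BJ, and 165 with MPEC and BJ. More were past 2-fold in the same direction, with 213 higher and 147 lower, 339 and 173, and 183 and 143 in that order. These ratios share the 1 library before co-culture, whose noise moves them the same way, so the counts do not show that the co-cultures acted alike. Small RNA genes are among them.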

How the results depend on the processing

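The use of the deposited limits, the count without MPEC and the settings without small RNA genes at the deposited level were chosen only after the data were seen. Of 168 recomputed counts under the 8 alternatives fixed beforehand, 145 stayed within 1.5 times the reported one. Among 848 ratios of named genes, none past 2-fold changed sign under any of them. This holds by construction, since a pseudocount or filter cannot change a sign. The scalings also differ too little between libraries to turn a 2-fold ratio. With a pseudocount of 5, 167 of the 848 fell under 2-fold. With a pseudocount of 5, which by construction shrinks the ratios of low genes, the numbers higher and lower were 257 and 186 for AKT-HUVEC against before, 424 and 259 for MPEC and 440 and 299 for BJ. They were 214 and 211 for AKT-HUVEC against BJ, 662 and 540 for MPEC against BJ, 367 and 365 for AKT-HUVEC against MPEC, and 52 and 59 after all 3. Against both others they were 292 and 241 for MPEC, 153 and 128 for BJ, and 76 higher for AKT-HUVEC. Without small RNA genes on the TPM scale there were 858 lower in MPEC than before, 794 lower in MPEC than in both others, and 58 higher and 17 lower in AKT-HUVEC than in both others. Leaving these genes out of the deposited values, which by construction removes calls, left 160 lower in AKT-HUVEC than before, 253 and 236 for AKT-HUVEC against BJ, 39 lower after all 3, and 31 and 9 for AKT-HUVEC against both others. With the rest also at a common sum at the deposited level there were 194 lower in AKT-HUVEC and 579 higher in MPEC than before, 248 higher in AKT-HUVEC than in BJ, 76 and 52 after all 3, and 31 and 8 for AKT-HUVEC against both others. The deposited limits by construction remove genes. Against before they left 318 higher and 241 lower for AKT-HUVEC, 568 and 449 for MPEC, and 560 and 527 for BJ. They left 65 higher after all 3, 66 and 70 for AKT-HUVEC against BJ, and 459 and 427 for MPEC against BJ. For AKT-HUVEC against MPEC they left 212 and 169. Against both others they left 5 and 0 for AKT-HUVEC, 154 and 161 for MPEC, and 60 and 46 for BJ. Without MPEC the shared genes were 339 and 173. The number of list medians that stood apart was 115 of 186 and stayed within 1.5 times of it under the 8 alternatives and the 2 added ones without small RNA genes. Of the 186, 135 kept their side of the random range in each of the 8 that gave a value, and 51 did not. With a filter of 5 FPKM 180 had a value, and the HOX list had none. A filter of 5 FPKM turned the endothelial list with MPEC to 0.0033, the intestinal list with AKT-HUVEC to 0.010, and the intestinal list of MPEC against BJ from 0.99 to -0.44. No filter turned the histone list of AKT-HUVEC against BJ to 0.0092, and the cause of these turns was not tested. On the TPM scale without small RNA genes the pluripotency list with MPEC was -0.023, but 0.34 for the same members at the deposited level, so scaling by itself did not give this turn. The median log2 ratio of all considered genes, MPEC against before, moved from 0.12 as deposited to -0.00 with upper quartile scaling and -0.04 without small RNA genes, and MPEC list medians are to be read against that shift. For MPEC against BJ it moved from 0.06 to -0.05 without small RNA genes. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for that reason. The BJ library, at 38.9 M fragments, had the lowest depth.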

Other observations

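The gene lists below were chosen only after some or all of their members had been seen, so their medians describe what drew attention, except that the values of the YAP targets had not been seen. Metallothioneins, which bind zinc and copper, were higher with BJ. Of 7 measured members 6 were at least 2-fold higher than before, with a median log2 ratio of 3.15, against 0.82 with AKT-HUVEC and 0.34 with MPEC. MT2A had 6.11 FPKM before, 10.02 with AKT-HUVEC, 9.08 with MPEC and 62.0 with BJ, and MT1X had 6.37, 20.7, 6.41 and 69.9. The copies are near-identical, so single values are uncertain. Muscle actins and myosin light chains had medians of -1.47, -2.57 and -1.87 over 8 genes. At least 2-fold lower were 4 with AKT-HUVEC, 6 with MPEC and 5 with BJ, and 1 was higher with BJ. MYL7 had 31.1 FPKM before, 19.9 with AKT-HUVEC, 1.199 with MPEC and 9.85 with BJ, while ACTA2 had 11.6, 10.8, 7.80 and 27.5. Gut hormone and peptide genes had medians of -0.52, -1.70 and -0.98 over 9 genes, and they did not move as one. For the same 9 genes at the deposited level, scaled to a common sum without small RNA genes, the medians were -0.600, -1.83 and -1.03. On the TPM scale without small RNA genes, where the values rise and TAC1 and VIP also pass the minimum of 1, they were -0.59, -0.97 and -0.94. GAST, for gastrin, had 16.9 FPKM before and 8.57, 4.53 and 2.80 after, and CCK, for cholecystokinin, 24.7 and 9.23, 6.90 and 3.004. PYY had 26.0 before and 140.3, 115 and 17.3 after, and NTS, for neurotensin, 68.2 and 47.3, 207 and 85.5. The signs of these medians against before held under the 4 other scalings.

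A hypothesis was that targets of YAP, a transcriptional coactivator that responds to cell shape and contact, are lower as a set with MPEC. It arose because CTGF, CYR61, TAGLN, CNN1 and THBS1 were low there, and it was tested on 17 other reported targets in no fixed list. Of these, 16 were measured, and their median with MPEC against before was -0.7792, below the random range of -0.14 to 0.35, with 7 at least 2-fold lower and 0 higher. ANKRD1 had 474 FPKM before, 202 with AKT-HUVEC, 127 with MPEC and 177 with BJ, and MYOF 71.6, 56.9, 15.7 and 49.0 in that order. ANKRD1 was thus lower in every co-culture. The hypothesis came from these same libraries, so the result describes them only. The median was -0.34 with AKT-HUVEC, also below its random range, so the lower level was not found in the MPEC library only. With BJ it was -0.18, inside the range, as it was at -0.22 and -0.23 when scaled to a common sum at the deposited level, with and without small RNA genes. On the TPM scale, where the pseudocount weighs less, it was -0.26 and -0.29, below the range. Lower YAP activity may be a candidate explanation, but these genes answer to other signals too, and a different mix of sorted cells stays open.

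Each library was also set against the other 3. The MPEC library had 407 genes at least 2-fold higher and 213 lower than in every other library, the BJ library 220 and 178, the library before co-culture 91 and 129, and the AKT-HUVEC library 73 and 29. Small RNA genes are among these. The 91 and 129 are the genes lower and higher after all 3 co-cultures, and leaving out small RNA genes left 39 and 102. The 73 and 29 are part of the 115 and 54 genes of AKT-HUVEC against both others, which fell to 31 and 9 in that way.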
